A study of Mus musculus with 8 samples.

How the data were processed

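Poly(A) RNA was sequenced from liver F4/80+ cells of 8 male mice aged 6.5 months, with 1 library per mouse. Per the labels' protocols, the liver was perfused, hepatocytes were spun out, and F4/80+ cells were picked from the remaining non-parenchymal cells with antibody-coated magnetic beads. F4/80 is a surface protein of tissue macrophages, and the selection aims at Kupffer cells (the resident macrophages of the liver) and other macrophages. Libraries had random-primed cDNA, per the labels' protocols, and a strand-marking step is not given in the sources used here, so overlapping genes on opposite strands were not told apart. The 4 control mice carried 1 floxed Ncoa5 allele and no Cre, and the 4 heterozygous mice carried the same allele with Cre in 1 copy of the lysozyme M (Lyz2) locus. Each library was assigned to its group by the genotype label.

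The authors deposited 1 table of normalized counts per gene, a signal that is never negative and has decimals. The submitters' processing notes name fastp 0.21.0 (read trimming), Salmon 1.3.0 (transcript quantification), DESeq2 1.28.1 (normalization and testing of counts) and the build GRCm38.p6, without parameters. Low values did not fall on a single step per library, so whole reads were not recovered and no count model was fitted. Library totals were 37.4 to 42.9 M normalized counts. The most frequent low value, taken as the approximate worth of 1 read, was 0.895 to 1.135, which puts the depth near 36.0 to 42.9 M reads per library. These depths are approximate, and no counting interval was derived from them. The table held 24234 rows, of which 6878 had no gene symbol. Symbols and coordinates for these came from the GENCODE M21 annotation of the same build, matched by Ensembl identifier, which left 39 rows without a symbol. The notation of gene symbols follows the table, so mitochondrial genes appear as ATP6 or ND1. A prefix shared by all value columns is not explained in the sources used here.

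The deposited values were used without further scaling. Genes with a mean of at least 10 over the 8 libraries were kept (15143 genes), and log2(value + 1) was tested for genotype with limma 3.58.1 in R 4.3.3, with an intensity trend and empirical Bayes moderation, two-sided. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. Differences are heterozygous minus control on the log2(value + 1) scale, which understates the change of low genes. The 3 genes chosen for single tests (Ncoa5, Lyz2 and Pf4) also had a two-sided exact permutation test of the mean log2 value over the 70 assignments of 4 of the 8 libraries, whose smallest possible p is 0.0286, adjusted over the 3 genes. The 50 gene lists (18 of cell type markers and 32 of pathways) were likewise fixed before the data were examined. Lists with at least 5 measured members were tested with camera (two-sided, preset inter-gene correlation of 0.01, adjusted over 48 lists), and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move, on balance, one way, and its mixed test whether they change in either direction.

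Genes to be named were chosen by a rule fixed before the data were examined. It takes Ncoa5, Lyz2 and Pf4; up to 12 passing genes per direction with a mean of at least 50 and no overlap between groups, filled to 8 by unadjusted p; the passing members of each list, at most 4; and the 3 members of lowest p of each called list in which none passed. Outside this rule, single markers of cell types (Clec4f, Timd4, Alb, Cd3d, Cd3e, Cd3g, Lck, Themis, Trac and Ppbp), COX1, Mmp13 and Hgf were taken from the lists, and Tmsb4x, Arhgap6, Mid1, Erdr1, Mospd2 and Tceanc from the region around 4 passing genes. Xist and Ddx3y served to check the sex of the libraries, and Lyz1 is mentioned as a paralog. Replicates were compared by Spearman correlation and principal components of the 1000 most variable genes. No 2 libraries were identical.

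The same code was tested on simulated data with the means and spreads of the 15143 genes and 200 genes changed between the groups. It recovered 0 of 200 genes changed by 0.5 on the log2 scale, 51.0% of those changed by 1, 73.0% of those changed by 2 and 94.0% of those changed by 4, with 0, 6, 9 and 12 false calls. With changes of 1 placed among genes of low spread, 98.5% were recovered with 8 false calls. In a simulation of independent genes with 3 lists shifted by 0.5, camera called all 3 and none of the other lists. The genes of a list are correlated in the data, with an estimate of 0.897 for hepatocyte genes. The simulation therefore does not show how often camera calls such lists falsely.

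Alternatives were the pseudocount (0.5 or 5), the filter (none, or a mean of at least 50), TMM scaling (own code, which recovered known factors within 0.183%) or quantile normalization, no variance trend, robust moderation, library weights, the replicate number as a block, and each library left out in turn. For the lists, an estimated correlation, fry, and leaving out members of several lists were added. A fit without both libraries that stood apart and a fit with the hepatocyte list mean as a covariate were chosen after seeing the data. Sequence reads were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.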

Results

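Messenger RNA of F4/80+ liver cells was profiled in 4 control mice and 4 mice labelled as carrying a deletion of 1 Ncoa5 allele in myeloid cells. NCOA5 (nuclear receptor coactivator 5) is a coregulator of nuclear receptors, and the deletion relies on Cre recombinase expressed from the lysozyme M locus, which is active in macrophages and granulocytes. The study concerns steatohepatitis and liver cancer in mice with reduced Ncoa5 in myeloid cells. The comparison asked which transcripts differed between the liver macrophages of the 2 genotypes. All mice were male, 6.5 months old and labelled C57BL/6. Library totals were 37.4 to 42.9 M normalized counts, and 15143 genes were tested with limma on log2(value + 1). Each value below is a mean ± SD of 4 mice in normalized counts, unless another unit is given, and the ± of a log2 difference of a gene is its SE by limma.

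The targeted gene, Ncoa5, measured 1281 ± 84.1 in control and 1288 ± 186 in heterozygous mice (ENSMUSG00000039804, chromosome 2, 165000357 to 165034867, GRCm38, minus strand). The log2 difference was -0.0016 ± 0.12 (SE), with a 95% interval from -0.28 to 0.28, so the level in heterozygous mice was 99.9% of control with an interval from 82.1% to 121.5%. No difference was detected (limma adjusted p = 0.998; exact permutation p = 1), and the sign of the difference turned with the library left out, from -0.0662 to 0.0919. The interval excludes a halving of the gene total, so the total gives no support for the deletion, but a smaller loss lies within it. The value sums reads over the whole gene, and the labels do not say which exons are removed. It also sums over all RNA of a library, which held hepatocyte transcripts (below). The total therefore does not by itself check the genotype labels.

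Lyz2, the lysozyme gene whose locus carries Cre, measured 180375 ± 30827 in control and 91295 ± 21977 in heterozygous mice (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand). All 4 heterozygous libraries lay below all 4 control libraries, and the level was 49.9% of control (95% interval 33.4% to 74.5%). The exact permutation p was 0.0286, the smallest the design allows, and 0.0429 after adjustment over the 3 genes tested singly. Over all genes tested, the limma adjusted p was 0.580. Lyz2 was chosen as a check of the genotype labels, because its locus carries Cre, and its values separated by label. Whether the lower level comes from the Cre insertion or from a change of the cells was not tested. Reads of Lyz2 can be shared with its paralog Lyz1.

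Pf4, a chemokine known from platelets that macrophages can also express, measured 88.4 ± 24.7 in control and 323 ± 69.4 in heterozygous mice (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383, plus strand). All 4 heterozygous libraries lay above all 4 control libraries, with a log2 difference of 1.88 (95% interval 1.26 to 2.51). The exact permutation p was 0.0286 and 0.0429 after adjustment over 3 genes, whereas over all genes the limma adjusted p was 0.137. With library weights that adjusted p was 0.0395, at a log2 difference of 1.86, and over the alternatives it ranged from 0.0395 to 0.620. Pf4 was chosen because the study's authors are known to have followed it up, which may rest on these same data. The permutation p adjusted over 3 genes is therefore no independent support.

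Between the genotypes, 6 of 15143 genes passed the test, 1 higher and 5 lower in heterozygous mice. Cd4, the T-cell coreceptor that some macrophages also carry, rose by 3.41 ± 0.35 on the log2 scale, from 33.8 ± 10.1 to 388 ± 203 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221, limma adjusted p = 0.0285). Negr1, a neuronal cell adhesion molecule, fell by 5.56 ± 0.60, from 705 ± 682 to 11.1 ± 5.57 (ENSMUSG00000040037, chromosome 3, 156561794 to 157316445, limma adjusted p = 0.0338). The other 4 lay near each other at the distal end of chromosome X. Of these, Tlr8, an endosomal receptor for single-stranded RNA, fell by 1.55 ± 0.17, from 14510 ± 1658 to 5028 ± 1200 (ENSMUSG00000040522, 167242696 to 167264329, limma adjusted p = 0.0363). Prps2, a phosphoribosyl pyrophosphate synthetase, fell by 1.03 ± 0.10, from 1838 ± 192 to 898 ± 8.37 (ENSMUSG00000025742, 167346322 to 167382749). Hccs, the enzyme that attaches haem to cytochrome c, fell by 1.02 ± 0.09, from 1350 ± 87.2 to 663 ± 28.5 (ENSMUSG00000031352, 169250193 to 169320372). Msl3, a subunit of a histone acetyltransferase complex, fell by 1.003 ± 0.09, from 2566 ± 182 to 1278 ± 50.8 (ENSMUSG00000031358, 168654117 to 168673898). The limma adjusted p was 0.0173 for each of these 3, and in all 6 genes the 4 mice of one genotype lay apart from the 4 of the other. Hccs overlaps Arhgap6 in the annotation, and reads in the overlap were not told apart.

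**Figure D1:**
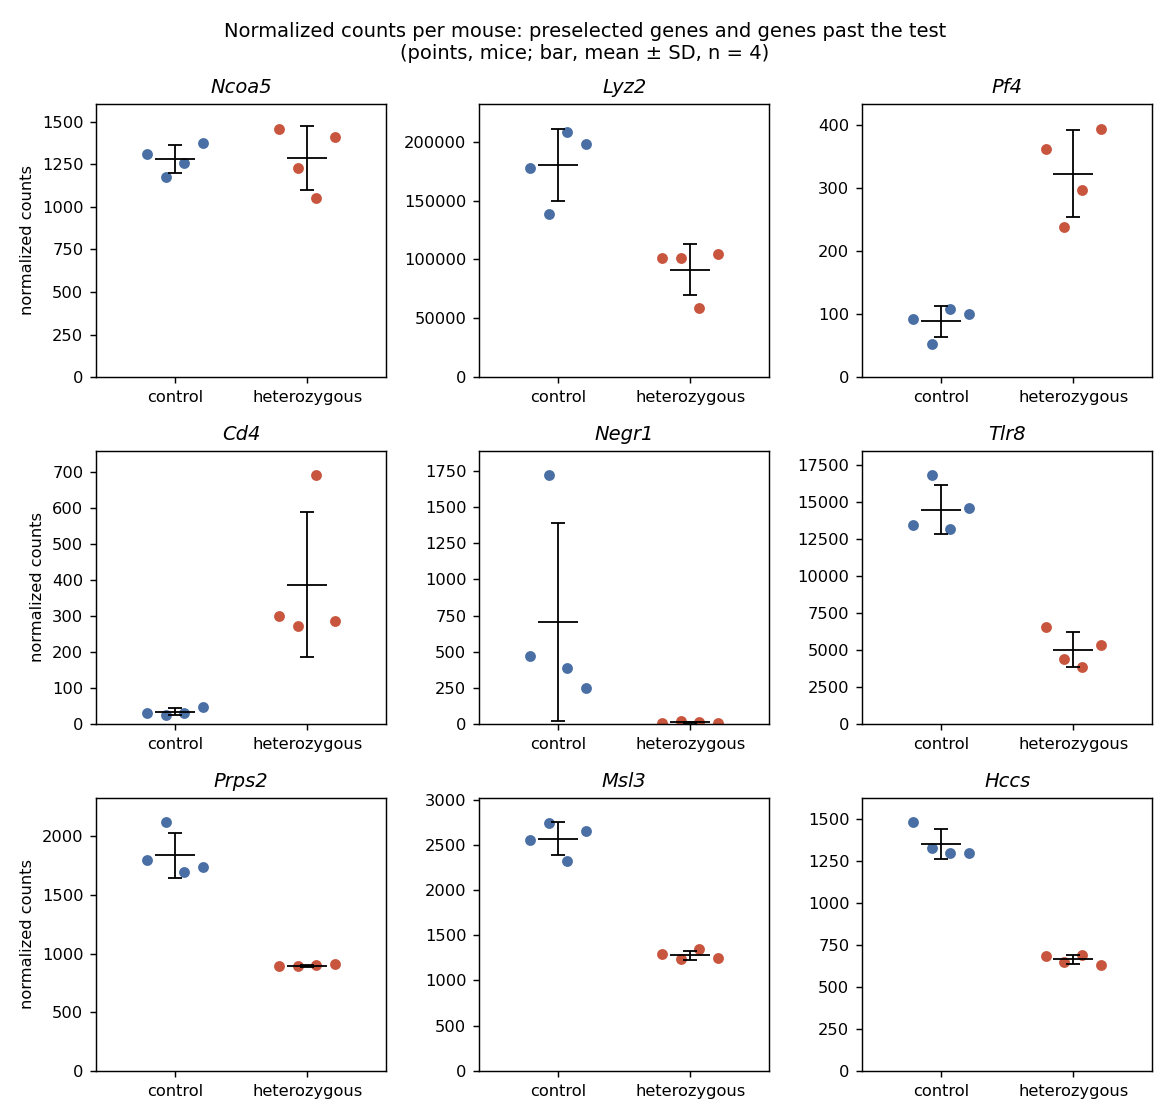
Normalized counts (y axis, linear from 0) of Ncoa5, Lyz2, Pf4 and the 6 genes past the test in control and heterozygous mice, with each point a mouse and bars the mean ± SD of 4. Ncoa5 overlaps between genotypes (1281 against 1288), whereas the groups lie apart in the other 8 panels, as for Msl3 at 2566 against 1278.

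With these 6 included, 1017 genes had an unadjusted p under 0.05, where 757 would be reached if none differed, and 396 of them were higher and 621 lower in heterozygous mice. The groups did not overlap in 778 genes, 5.14% of those tested, against 2.86% by chance. The excess at an unadjusted p under 0.05 (limma) also arises between other groupings. Of the 34 other splits of the libraries into 4 and 4, 5 gave more than 1017 such genes, up to 2741. Genes without overlap were not counted in the other splits. The number of passing genes varied with the library left out. It was 0 when control 1, control 3, heterozygous 1, heterozygous 2 or heterozygous 4 was left out (685, 1078, 1249, 840 and 710 genes at an unadjusted p under 0.05 by limma) and 10 without control 4. It was also 0 without the 2 libraries that stood apart (below), with 933 genes at an unadjusted p under 0.05 by limma. With the replicate number as a block it was 0 as well, with 1499 such genes. The log2 differences of the 6 genes kept their sign in every alternative. With 1 library left out, the log2 difference stayed between 3.09 and 3.59 for Cd4, -5.92 and -4.99 for Negr1, -1.69 and -1.43 for Tlr8, -1.06 and -0.96 for Prps2, -1.04 and -0.98 for Hccs and -1.05 and -0.97 for Msl3. The control mean of Negr1 was 367 without control 2.

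Among genes that did not pass but had the lowest unadjusted p with separated groups, 6 besides Pf4 had higher values in heterozygous mice. Slc1a2, a glutamate transporter, measured 938 ± 271 and 2848 ± 880, and Pianp measured 287 ± 142 and 980 ± 159. Angptl7, an angiopoietin-like secreted protein, measured 341 ± 125 and 879 ± 155, and Smim1 measured 76.3 ± 29.7 and 292 ± 45.0. Rab34, a small GTPase, measured 68.5 ± 33.1 and 215 ± 37.4. The mitochondrial ATP6 measured 40174 ± 9843 and 93026 ± 21243. Their limma adjusted p lay between 0.199 for Pianp and 0.367 for Rab34. In the other direction, Tlr7, a receptor for single-stranded RNA and neighbour of Tlr8, measured 12288 ± 2353 in control and 5292 ± 716 in heterozygous mice (limma adjusted p = 0.0888). Coro1a, an actin regulator of leukocytes, measured 11435 ± 2589 and 5023 ± 664 (limma adjusted p = 0.138). LOC105245440 (ENSMUSG00000113136) measured 138 ± 66.0 and 16.1 ± 8.53 (limma adjusted p = 0.236).

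Of the 11 tested genes from Tmsb4x to the chromosome end (X, 167207093 to 170019281), 10 had lower values in heterozygous mice, with a median log2 difference of -1.02, and 7 had no overlap between groups. Tmsb4x, which encodes the actin-binding peptide thymosin beta 4, measured 244048 ± 18615 in control and 109808 ± 18169 in heterozygous mice (log2 difference -1.16 ± 0.20, limma adjusted p = 0.277). Mid1, which reaches into the pseudoautosomal region, had a log2 difference of -0.65 ± 0.28, and the X-linked copy of the pseudoautosomal Erdr1 (ENSMUSG00000095562) had 0.02 ± 0.37. The 8 tested genes next to the segment, whose last gene Tceanc ends at 166518567, had a median of 0.12 and lay between -0.10 and 0.82. The other 417 tested genes of chromosome X had a median of -0.00651. Among 14893 other windows of 11 consecutive tested genes, 2 had a median as low, on chromosome 6 (-1.37) and chromosome 12 (-1.07), and the highest was 2.09. Both low windows lie at immunoglobulin loci, and 10 of the 11 genes of the former and all 11 of the latter are immunoglobulin genes. This region was described after its values were seen.

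**Figure D2:**
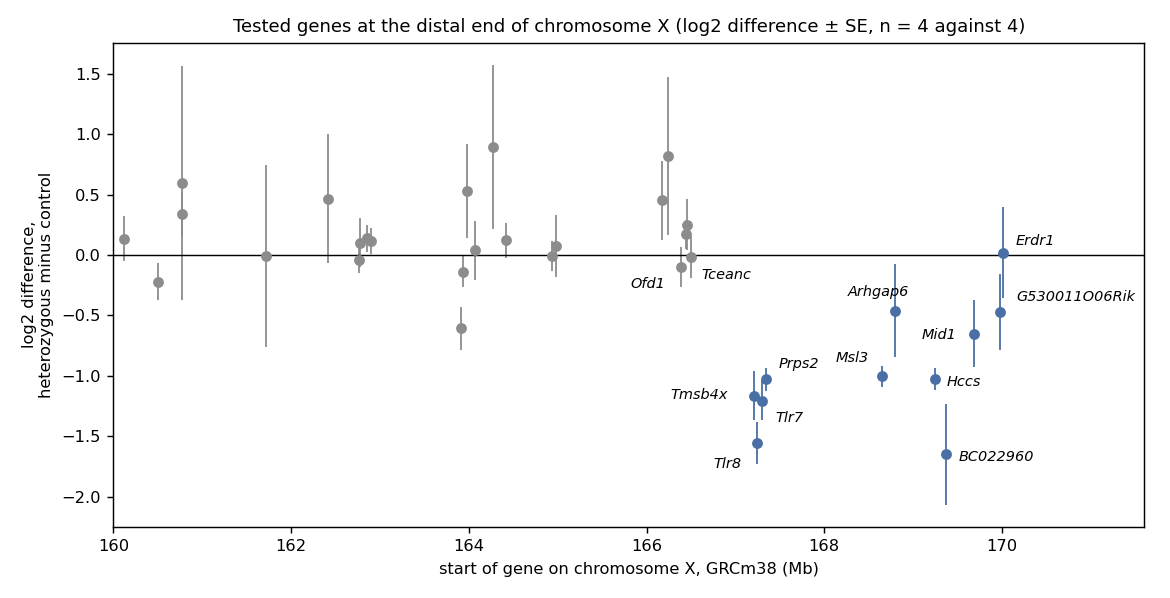
Log2 difference (heterozygous minus control, ± SE, 4 against 4 mice) of each tested gene from 160 Mb to the distal end of chromosome X, plotted at its start in GRCm38. Blue points run from Tmsb4x at -1.16 to Erdr1 at 0.02, and 10 of these 11 lie below 0, whereas the grey neighbours from Mospd2 to Tceanc lie between -0.10 and 0.82.

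Each library held Kupffer cell transcripts beside a variable share of hepatocyte transcripts. The 28 genes of Kupffer cell identity (such as Clec4f, 264050 ± 115270 in control, or 318320 without control 2, and 337520 ± 49320 in heterozygous mice) made up 3.04% to 6.31% of each library, and the 26 hepatocyte genes 0.968% to 6.77%. The hepatocyte share exceeded the Kupffer share in control 2 (4.44% against 3.04%) and heterozygous 3 (6.77% against 3.50%), and in the latter the albumin gene Alb measured 1014700. Control 2 stood apart on the first principal component (33.25% of the variance), with a Kupffer list mean of 13.6 where the other control libraries had 14.9 to 15.1. In that library Timd4, an efferocytosis receptor of resident Kupffer cells, measured 275, against 23100 to 29780 in the other controls. Its neutrophil and erythroid list means were the highest of the 8 libraries, at 7.955 and 9.20. Heterozygous 3 stood apart on the second component (31.0%), with the highest hepatocyte share (6.77%) and a Kupffer list mean of 14.4 where the other 3 had 15.0 to 15.1. Xist was at most 7.27 and the Y-linked Ddx3y at least 4979 in each library, and Spearman correlations between libraries were 0.926 to 0.991.

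**Figure D3:**
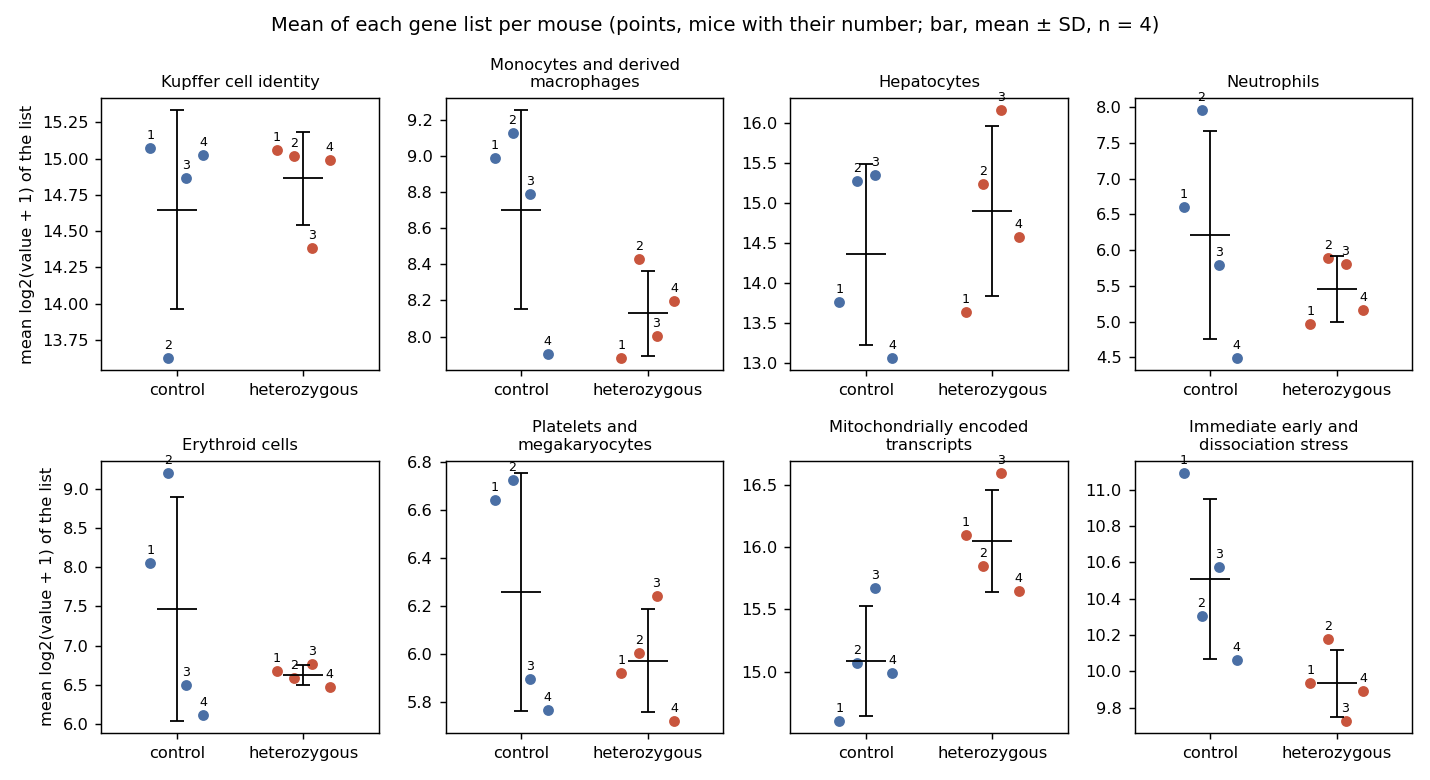
Mean log2(value + 1) of 8 gene lists per mouse (y axes do not start at 0), with the number of each mouse beside its point and bars for the mean ± SD of 4. Control 2 has the lowest Kupffer list mean (13.6) and the highest neutrophil mean (7.955), and heterozygous 3 the highest hepatocyte mean (16.2).

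With the preset correlation, camera called 19 of the 48 lists tested, 6 higher and 13 lower in heterozygous mice. None was called with an estimated correlation (adjusted p = 0.744 for each of the 19, and 0 lists with an unadjusted p under 0.05) or by fry (lowest adjusted p = 0.554, with 1 list at an unadjusted p under 0.05). After quantile normalization 9 lists were called higher and 9 lower, and without control 2 and heterozygous 3 the count was 11. The mitochondrially encoded, immediate early, monocyte, lipid-associated macrophage and Toll-like receptor lists were called in every other alternative. The mixed test of fry called 1 list, T cells (adjusted p = 0.000138), in which Cd4 was the gene that passed. Over all genes tested, a member passed in 2 lists, Cd4 among the T-cell markers and Tlr8 among the Toll-like receptor genes. Counts given as "adjusted over the list alone" are named where they exceed 0, and were 0 in each list for which none is given.

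Mitochondrially encoded transcripts had the largest mean of the higher lists, with all 13 members positive, a mean log2 difference of 0.96 and a camera adjusted p of 3.24e-12 (adjusted p = 0.744 with an estimated correlation). Adjusted over the list alone, 12 of 13 rose, and COX1 did not pass. With 1 library left out that number was 1, 5, 12 and 1 without controls 1 to 4 and 10, 9, 7 and 10 without heterozygous 1 to 4, and ATP6 passed each time. ND1 measured 63661 ± 17946 in control and 115573 ± 25722 in heterozygous mice, and ND6 measured 9145 ± 2679 and 17645 ± 5216 (limma adjusted p over all genes = 0.618 and 0.611). These transcripts made up 1.89% to 3.80% of control and 3.88% to 6.23% of heterozygous libraries. The library means of the list overlapped between genotypes, at 15.67 in control 3 and 15.65 in heterozygous 4. Reads of mitochondrial genes can be shared with nuclear copies. The nuclear genes of oxidative phosphorylation were positive in 28 of 30 members with a mean of 0.19 (camera adjusted p = 0.00259; adjusted p = 0.744 with an estimated correlation), among them Ndufa2 at 0.35 ± 0.20, Uqcrq at 0.51 ± 0.34 and Ndufa1 at 0.23 ± 0.15. Without heterozygous 3 these 3 genes had 0.17, 0.17 and 0.11 and the list mean was -0.000295, and with the hepatocyte list mean as a covariate it was 0.0926, neither of them called.

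Hepatocyte genes were positive in 24 of 26 members, with a mean of 0.54 (camera adjusted p = 0.0165; adjusted p = 0.744 with an estimated correlation). The library means of this list overlapped between genotypes, at 14.4 ± 1.13 and 14.9 ± 1.06. Ass1 of the urea cycle measured 18040 ± 11367 in control and 34372 ± 26683 in heterozygous mice, Cyp3a11 measured 16097 ± 12863 and 33301 ± 30247, and the transferrin gene Trf measured 100771 ± 44090 and 149457 ± 68536. Without heterozygous 3 the heterozygous means were 21519, 18440 and 116890, and without control 1 the control means of Ass1 and Cyp3a11 were 21832 and 20472. The call of the list was lost without control 1, control 4, heterozygous 2 or heterozygous 3, where the mean was 0.34, 0.11, 0.43 and 0.12. Without control 2, control 3 or heterozygous 1 it was 0.84, 0.87 and 0.96. Beside this higher hepatocyte mean, fatty acid oxidation was positive in 23 of 24 members, with a mean of 0.42 (camera adjusted p = 0.00246; adjusted p = 0.744 with an estimated correlation), among them Hadha at 0.30 ± 0.19, Cpt2 at 0.58 ± 0.37 and Hadh at 0.69 ± 0.45. Cholesterol biosynthesis was positive in 21 of 24, with a mean of 0.52 (camera adjusted p = 0.00259; adjusted p = 0.744 with an estimated correlation). Its enzymes Hmgcs1 and Pmvk had log2 differences of 0.98 ± 0.44 and 0.80 ± 0.41, whereas the transcription factor Srebf2 had -0.46 ± 0.16. Without heterozygous 3 neither metabolic list was called, at means of 0.0711 and 0.21, with 0.12 for Hadha, 0.20 for Cpt2, 0.21 for Hadh, 0.54 for Hmgcs1 and 0.44 for Pmvk, and cholesterol biosynthesis was also lost without control 4 (0.26). Without heterozygous 1 the means were 0.64 and 0.81. With the hepatocyte list mean as a covariate the fatty acid oxidation mean was 0.18 and not called, and the cholesterol biosynthesis mean was 0.20 and still called. Heat shock and chaperone genes were positive in 15 of 16, with a mean of 0.26 (camera adjusted p = 0.0196; adjusted p = 0.744 with an estimated correlation), among them Cryab at 0.84 ± 0.24, Dnajb4 at 0.49 ± 0.21 and Bag3 at 0.21 ± 0.16. That call was lost without control 3 (mean 0.15, and 0.12 for Bag3) or heterozygous 1 (0.21). Without heterozygous 3 Dnajb4 had 0.27 and Bag3 0.13.

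Among the 13 lower lists, immediate early and dissociation stress genes were negative in 20 of 24 members, with a mean of -0.58 (camera adjusted p = 2.35e-06; adjusted p = 0.744 with an estimated correlation). Dusp2, a MAP kinase phosphatase, measured 541 ± 302 in control and 158 ± 22.4 in heterozygous mice, Nr4a2 measured 171 ± 80.9 and 60.1 ± 19.02, and Egr3 measured 222 ± 127 and 76.1 ± 28.3. Without control 1, whose mean of this list was the highest (11.1), the difference was -0.38 and still called. Monocyte and monocyte-derived macrophage markers were negative in 17 of 20, with a mean of -0.57 (camera adjusted p = 5.54e-05; adjusted p = 0.744 with an estimated correlation). The lectin receptor Clec4e measured 140 ± 149 in control and 17.4 ± 2.30 in heterozygous mice, Ace measured 263 ± 109 and 109 ± 29.6, and the integrin Itgam measured 6651 ± 1941 and 3576 ± 1128. Lipid-associated macrophage genes were negative in 15 of 20, with a mean of -0.40 (camera adjusted p = 0.00259; adjusted p = 0.744 with an estimated correlation). The lipase Lpl measured 56372 ± 4980 in control and 37966 ± 9257 in heterozygous mice, the actin-capping gene Capg measured 3845 ± 490 and 2857 ± 246, and Itgax (CD11c) measured 4916 ± 7582 and 307 ± 48.8. Without control 2 both lists were still called, at means of -0.37 for monocytes and -0.15 for lipid-associated macrophages. The library means of both lists and of the immediate early list overlapped between genotypes. Control 4 had 7.90 for monocytes, 10.49 for lipid-associated macrophages and 10.06 for immediate early genes. The highest heterozygous means were 8.43, 10.89 and 10.18. Control 2 carries most of the control means of Clec4e (359 in that library) and Itgax (16253). Without it these means were 66.8 and 1136.5, and the log2 differences went from -2.40 to -1.76 and from -2.61 to -1.57. In control 4 Itgax measured 306, within the range of the heterozygous libraries.

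Toll-like receptor and NF-kB genes were negative in 22 of 29 members, with a mean of -0.22 (camera adjusted p = 0.000166; adjusted p = 0.744 with an estimated correlation), and Tlr8 and Tlr7 fell when adjusted over the list alone. Both lie in the X-linked segment. The list was still called without heterozygous 3, at a mean of -0.13, and without control 2 and heterozygous 3 together, at -0.11. Proinflammatory cytokines, chemokines and enzymes were negative in 15 of 23, with a mean of -0.38 (camera adjusted p = 0.00334; adjusted p = 0.744 with an estimated correlation), and Il12b fell when adjusted over the list alone, from 119 ± 70.1 to 20.0 ± 2.84. Tnf measured 351 ± 144 in control and 138 ± 33.1 in heterozygous mice, and Socs3 measured 920 ± 642 and 257 ± 96.3. Il12b did not pass over the list without control 2, heterozygous 2, heterozygous 3 or heterozygous 4 (-2.10, -2.23, -2.30 and -2.34). Without control 1 or heterozygous 3 this list was not called (means -0.19 and -0.26). Checkpoint and immunosuppressive molecules were negative in 9 of 14, with a mean of -0.42 (camera adjusted p = 0.0130; adjusted p = 0.744 with an estimated correlation), and Pdcd1lg2, which encodes the ligand PD-L2, fell when adjusted over the list alone, from 426 ± 616 to 14.7 ± 10.8. Cd274, which encodes PD-L1, measured 4076 ± 905 and 2667 ± 682, and Il10 measured 132 ± 14.5 and 86.0 ± 29.0. Without control 2, where Pdcd1lg2 measured 1349, its control mean was 118 and its log2 difference -3.09 in place of -3.98, still past the test over the list. The heterozygous mean of Pdcd1lg2 was 9.43 without heterozygous 1, at a log2 difference of -4.38. Pdcd1lg2 did not pass without heterozygous 2, heterozygous 3 or heterozygous 4 (-3.87, -3.73 and -3.92). Il10 went from -0.68 to -0.40 without heterozygous 3. Without control 2 the list was not called (mean -0.25).

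Type I interferon response genes were negative in 23 of 26 members, with a mean of -0.18 (camera adjusted p = 0.00277; adjusted p = 0.744 with an estimated correlation), among them Ifih1 at -0.30 ± 0.10, Ifit3b at -0.37 ± 0.15 and Ifit3 at -0.34 ± 0.16. Ifit3 and Ifit3b are near-identical copies that can share reads. TGF-beta and SMAD signalling was negative in 18 of 22, with a mean of -0.15 (camera adjusted p = 0.00332; adjusted p = 0.744 with an estimated correlation), among them Bmpr2 at -0.40 ± 0.12, Smad7 at -0.35 ± 0.13 and Id2 at -0.60 ± 0.23. Neither was called without heterozygous 3 (means -0.0844 and -0.11), nor was the interferon list without control 4 (-0.0441) or with the hepatocyte list mean as a covariate (-0.0461). Without control 2 or heterozygous 1 the interferon mean was -0.33 and -0.28. Ifit3b and Ifit3 had -0.24 and -0.21 without control 4, and Id2 had -0.36 without control 2. Ribosomal protein genes were negative in 28 of 33, with a mean of -0.0510 (camera adjusted p = 0.00835; adjusted p = 0.744 with an estimated correlation), among them Rplp0 at -0.18 ± 0.11, Rpl5 at -0.20 ± 0.11 and Rps23 at -0.20 ± 0.13. Their mean was positive without control 2 (0.0278) or heterozygous 4 (0.0124), and not called without control 1 (-0.0160), and it was -0.15 without control 3 and -0.0780 without heterozygous 1. Rps23 had -0.11 without control 2. Cell cycle genes were negative in 28 of 32, with a mean of -0.25 (camera adjusted p = 0.0155; adjusted p = 0.744 with an estimated correlation), among them Tk1 at -0.26 ± 0.13, Aurka at -0.43 ± 0.28 and Cdc20 at -0.52 ± 0.35. Their mean was 0.0170 without control 1, where Aurka had -0.21 and Cdc20 -0.28, and the call was also lost without control 4, heterozygous 3 or heterozygous 4 (-0.19, -0.14 and -0.0865). With the hepatocyte list mean as a covariate it was -0.0509 and not called, and without control 2 or heterozygous 1 it was -0.47 for each.

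The remaining lower lists had camera adjusted p close to the threshold. Inflammasome and pyroptosis genes had a mean of -0.13 (camera adjusted p = 0.0372; adjusted p = 0.744 with an estimated correlation), with 13 of 18 negative, among them Nek7 at -0.22 ± 0.09, Il18 at -0.25 ± 0.11 and Pycard at -0.42 ± 0.23. Nuclear receptors and coregulators other than Ncoa5 had a mean of -0.0625 (camera adjusted p = 0.0372; adjusted p = 0.744 with an estimated correlation), with 18 of 25 negative, among them Rara at -0.35 ± 0.12, Ncor2 at -0.36 ± 0.15 and the oxysterol receptor gene Nr1h3 at -0.42 ± 0.16. Macrophage lineage transcription factors had a mean of -0.13 (camera adjusted p = 0.0401; adjusted p = 0.744 with an estimated correlation), with 14 of 21 negative, among them Nr4a1 at -1.29 ± 0.46 and Klf4 at -0.93 ± 0.34. Each of these 3 was lost without control 3 or heterozygous 3, at means of -0.13 and -0.00103 for the inflammasome, -0.0238 and -0.0606 for nuclear receptors and -0.0901 and -0.0783 for transcription factors. Further losses came without control 1 or control 4 for the inflammasome (-0.10 and -0.11), control 4 for nuclear receptors (-0.0942, against -0.0938 without control 1 and -0.0380 without control 2, where the call held), and control 1 or heterozygous 1 for transcription factors (-0.0867 and -0.12). With the hepatocyte list mean as a covariate none of the 3 was called, at means of -0.0654, -0.0945 and -0.13. Pycard had -0.18 without control 2 and -0.0999 without both libraries that stood apart, Ncor2 had -0.22 without heterozygous 3 and Klf4 -0.61 without control 1.

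**Figure D4:**
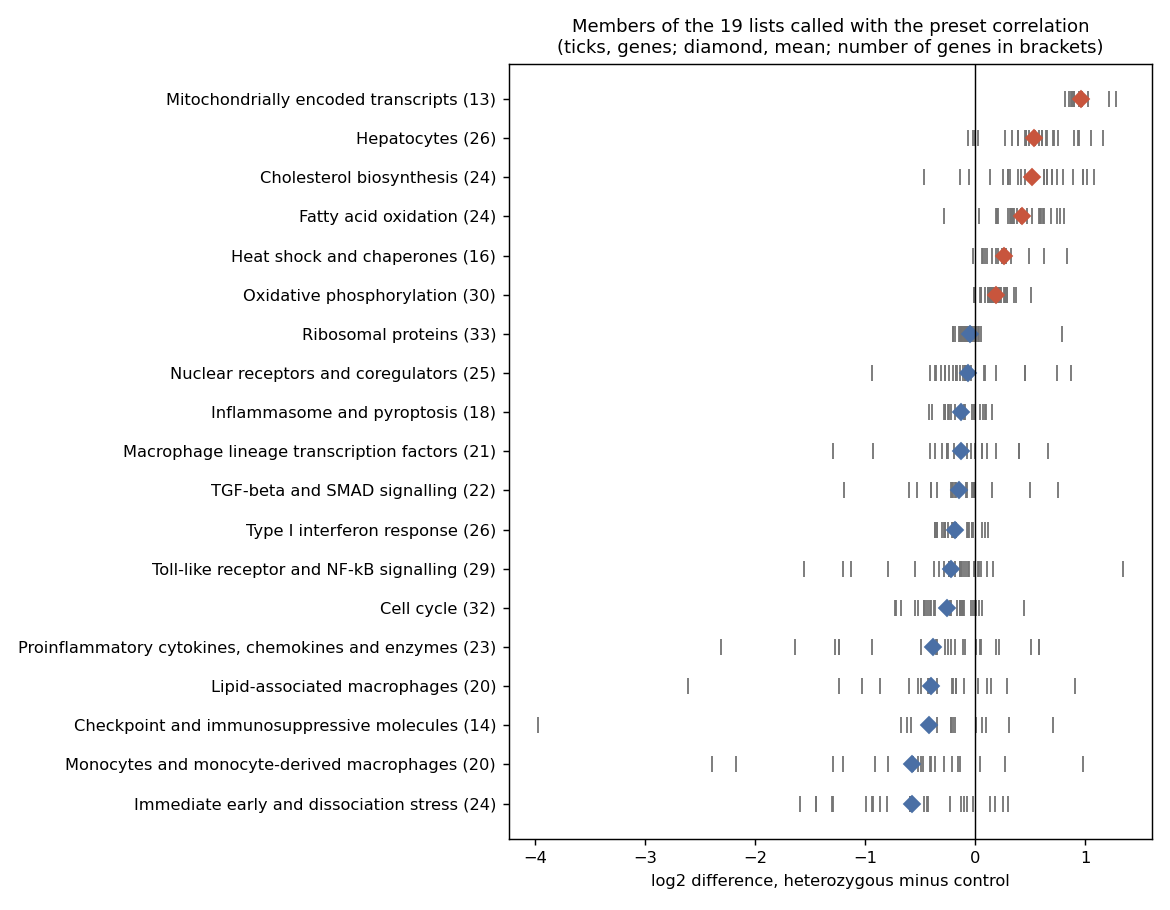
Log2 difference (x axis, heterozygous minus control) of each measured member (ticks) of the 19 lists that camera called with the preset correlation, with the mean as a diamond and the number of members in brackets. The mean runs from 0.96 for mitochondrially encoded transcripts to -0.58 for immediate early genes, and none of the lists was called with an estimated correlation.

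The other 29 lists were not called. Of the cell type lists, Kupffer cell identity had a mean log2 difference of 0.22 (camera adjusted p = 0.398), sinusoidal endothelial cells -0.0793 (0.458), stellate cells and fibroblasts 0.0903 (0.549) and cholangiocytes 0.0287 (0.882). The lymphoid means were 0.74 for T cells (camera adjusted p = 0.0537), -0.0215 for B cells (0.818) and -0.63 for plasma cells (0.0522). Cd4 rose in the T-cell list, also when adjusted over the list alone, and of the 7 other tested markers 5 were positive and 2 negative. Themis, a regulator of T-cell development, measured 16.5 ± 14.9 and 94.6 ± 122, with 274 in heterozygous 3, the library with the highest Cd4, and a heterozygous mean of 34.7 without it. The control mean of Themis was 9.06 without control 4. Cd3g measured 11.4 ± 8.49 and 14.9 ± 9.79 and Lck 21.7 ± 8.62 and 27.8 ± 5.53. Below the minimum mean of the test, Cd3e measured 2.63 ± 2.30 and 8.89 ± 6.91, Cd3d 5.71 ± 1.62 and 12.9 ± 16.8, and Trac 12.9 ± 8.17 and 6.37 ± 2.05. Neutrophil markers had a mean of -0.76 (camera adjusted p = 0.139), erythroid markers -0.84 (0.141), eosinophil markers -0.61 (0.156), conventional dendritic cell markers -0.0601 (0.561) and plasmacytoid dendritic cell markers -0.24 (0.713). Platelet and megakaryocyte markers had a mean of -0.28 (camera adjusted p = 0.185), and Pf4 rose in that list when adjusted over the list alone, whereas Ppbp measured 28.7 ± 15.0 and 9.95 ± 6.47. Without control 2 the means were -0.12 for Kupffer cell identity, 0.0771 for neutrophils and 0.0263 for erythroid cells, so the signs above rest on that library. With 1 library left out, 8 of these cell type lists were called at least once. They were plasma cells without control 1, control 4 or heterozygous 3 (-0.71, -0.91 and -0.86), T cells without control 2, control 4 or heterozygous 4 (0.83, 0.85 and 0.79) and erythroid cells without control 3 or control 4 (-1.16 and -1.29). The others were neutrophils and platelets without control 4 (-1.33 and -0.45), stellate cells without control 1 (0.23), and Kupffer and sinusoidal endothelial cells without heterozygous 3 (0.38 and -0.25). In the other direction, the T-cell mean was 0.45 without heterozygous 3, the means of plasma cells, platelets and plasmacytoid dendritic cells were -0.39, -0.13 and -0.13 without control 2, and those of erythroid cells and platelets -0.46 and -0.16 without control 1. The eosinophil mean was -0.0218 without control 1, where too few members were left to test. The plasmacytoid dendritic cell mean was -0.47 without control 4. Leaving out 1 library gave from -0.25 (without heterozygous 3) to 0.0762 (heterozygous 1) for sinusoidal endothelial cells, from -0.0234 (heterozygous 4) to 0.23 (control 1) for stellate cells and from -0.42 (control 4) to 0.46 (heterozygous 1) for cholangiocytes. It gave from -0.0922 (control 2) to 0.0883 (control 3) for B cells and from -0.10 (control 2) to -0.00550 (control 1) for conventional dendritic cells. The NK cell list had 2 measured members and the basophil and mast cell list 3, too few to test.

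Of the pathway lists that were not called, the unfolded protein response had a mean of 0.18 (camera adjusted p = 0.0592), fatty acid synthesis and lipid storage 0.59 (0.0745), MHC class II presentation 0.30 (0.121), the circadian clock 0.28 (0.236), scavenging and efferocytosis receptors 0.28 (0.480) and the NRF2 response 0.29 (0.561). Lysosome and autophagy had a mean of -0.0855 (camera adjusted p = 0.0716), p53 targets -0.21 (0.0737) and glycolysis and hypoxia -0.0825 (0.188). Profibrotic and growth factors had 0.10 (camera adjusted p = 0.549), and adjusted over the list alone Mmp13, a collagenase, rose (35.6 ± 22.9 to 164 ± 53.02) and Hgf, the hepatocyte growth factor gene, fell (2346 ± 171 to 1628 ± 261). Without control 1, heterozygous 1 or heterozygous 4 neither passed (2.34, 2.28 and 2.33 for Mmp13 and -0.54, -0.58 and -0.54 for Hgf), nor did Mmp13 without heterozygous 3 (2.30) or Hgf without control 2 or control 3 (-0.51 for each). In 7 lists the median, the mean and the camera direction did not share a sign. Alternative activation had a median of 0.0248 and a mean of -0.17 (camera adjusted p = 0.470), with Pdcd1lg2 falling when adjusted over the list alone, which was lost without control 1, control 3, heterozygous 2, heterozygous 3 or heterozygous 4 (-4.21, -4.17, -3.87, -3.73 and -3.92). Iron and haem handling had -0.0897 and 0.00566 (0.522), conventional dendritic cells 0.0158 and -0.0601, and complement 0.12 and -0.0317 with camera upwards (0.925). LXR targets had 0.0848 and 0.0321 (0.667) and the interferon gamma response 0.0540 and 0.0478 (0.882), both with camera downwards, and insulin and IGF signalling had -0.0241 and 0.0443 with camera downwards (0.856). With 1 library left out, 14 of the 29 lists not called changed the sign of their mean and 16 were called at least once, 8 of them pathways. The latter were fatty acid synthesis without control 2, heterozygous 1 or heterozygous 2 (0.78, 0.75 and 0.76), the unfolded protein response without control 4 or heterozygous 2 (0.14 and 0.23), MHC class II and p53 targets without control 4 (0.54 and -0.34) or heterozygous 3 (0.36 and -0.30), and lysosome without control 3 or heterozygous 1 (-0.11 and -0.13). They also included the circadian clock without heterozygous 1 (0.50), glycolysis without heterozygous 3 (-0.18), and the interferon gamma response in opposite directions without control 2 (-0.14) and control 4 (0.23). In the other direction, without heterozygous 3 the means were 0.25 for fatty acid synthesis, 0.11 for the unfolded protein response, 0.0423 for the circadian clock and 0.0600 for the NRF2 response, none of them called. Without control 2 they were 0.0507 for MHC class II, -0.0690 for p53 targets, -0.0950 for scavenging receptors, 0.0190 for glycolysis and 0.0503 for profibrotic factors, also not called. Scavenging receptors had 0.44 without control 1, profibrotic factors 0.22 without control 3, glycolysis -0.19 without control 4 and -0.0109 without heterozygous 1, and the circadian clock 0.17 without control 1 and 0.18 without control 4. The lists with a mean near 0 ran from -0.0748 (without control 4) to 0.0836 (heterozygous 1) for iron, from -0.0692 (heterozygous 3) to 0.15 (control 2) for LXR targets, from 0.01003 (heterozygous 3) to 0.0776 (control 3) for insulin signalling and from -0.0464 (heterozygous 4) to 0.14 (heterozygous 1) for complement. Alternative activation ran from -0.30 (control 2) to 0.0375 (control 1).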

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

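Values of the named genes, the list means per library and the library totals were examined within each group of 4 libraries for a library whose gap to its nearest neighbour, divided by the range of the group, exceeded the critical value of Dixon's test for 4 values at 0.05. Of 182 such groups 12 did, where chance gives about 9.1, and no explanation was tested for them.

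Heterozygous 3 was the distant library in 5. Lyz2 measured 58430 there against 101020 to 104680 in the other 3 heterozygous libraries (ratio 0.939), and Cd4 measured 692 against 273 to 300.1 (0.8995). Dnajb4 measured 1365 against 733 to 784 (0.893), Ncor2 measured 2699 against 3875 to 4081 (0.874), and the Kupffer cell list mean was 14.4 against 15.0 to 15.1 (0.898). Control 1 was distant for Rara at 1638 against 1295 to 1316 (0.932), Capg at 4574 against 3545 to 3682 (0.852) and Hccs at 1479 against 1298 to 1326 (0.834). Control 2 was distant for the Kupffer cell list mean, 13.6 against 14.9 to 15.1 (0.857). Heterozygous 1 was distant for Aurka at 145 against 96.6 to 101.4 (0.880), heterozygous 4 for Dusp2 at 125 against 164 to 173 (0.839), and heterozygous 2 for the eosinophil list mean at 7.19 against 6.32 to 6.46 (0.845).

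Gm49393, a gene model on chromosome 13 below the minimum mean of the test, passed when the filter was dropped (limma adjusted p = 0.0171). It measured 17.05 ± 5.52 in the 4 heterozygous libraries and was listed at 0 in all 4 control libraries, and its difference on the log2(value + 1) scale was 4.12, which depends on the pseudocount.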

How the results depend on the processing

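The fits without both libraries that stood apart and with the hepatocyte list mean as a covariate were chosen after seeing the data. Of 1340 values under an alternative of the 67 named genes other than Ncoa5, Lyz2 and Pf4, 1281 kept direction and side of the threshold, 50 lost the call, 9 gained it and 0 changed sign; of 60 values of Ncoa5, Lyz2 and Pf4, 52 kept both, 1 gained the call and 7, all of Ncoa5, changed sign; of 436 list values, 335 kept both, 96 lost the call and 5 changed sign. The causes were not tested, except that leaving out a library leaves fewer residual degrees of freedom. In the self-test, 0 of 200 changes of 0.5 on the log2 scale were recovered among genes drawn at random from all tested. Changes of 0.5 among genes of low spread were not simulated. The number of genes changed (6) stayed between 5 and 7 under the pseudocount, filter, scaling, trend and robust alternatives. It was 21 with library weights, 10 with the hepatocyte covariate and 0 without both libraries that stood apart, and from 0 to 10 when 1 library was left out. No pairing of the mice is stated in the labels, and the correlations of same-numbered libraries did not settle it. They were 0.383, -0.0882, 0.295 and 0.120, and only numbers 1 and 3 correlated best with their own. With the number as a block, 0 genes passed (1499 at an unadjusted p under 0.05 by limma) and 20 lists were called. The number of lists (19) was 11 without both libraries that stood apart, 0 with an estimated correlation, 0 by fry, from 14 to 22 when 1 library was left out and from 14 to 21 otherwise. Lyz2 stayed between -1.20 and -0.80 and did not pass over all genes. Pf4 lay between 1.65 and 2.02 when 1 library was left out and passed with library weights (1.86). Ncoa5, near 0, changed sign with library weights (0.0565), without both libraries that stood apart (0.0525), with the hepatocyte covariate (0.0695) and when 1 library was left out (-0.0662 to 0.0919). List means that changed sign when 1 library was left out were oxidative phosphorylation (-0.000295 to 0.28), ribosomal proteins (-0.15 to 0.0278, and 0.00729 without both libraries that stood apart) and cell cycle (-0.47 to 0.0170). The hepatocyte list gave no value with its own mean as the covariate. Depth was similar between libraries and approximate, which limits genes near the minimum mean.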

Other observations

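The genes of the first 2 paragraphs and the patterns weighed below were chosen after the results were seen, as were the tests of Pf4 and of hepatocyte RNA as the whole cause, whereas the other tests were written down before their own results were known. Of genes with large differences, Fcrl5, Itgad, Sh2d1b1 and Klrb1b had low values in all 4 heterozygous libraries, the highest value in control 2, which stood apart, and the lowest control value in control 4. Fcrl5, an Fc receptor-like protein, measured 8268 in control 2, 863 and 798 in controls 1 and 3 and 32.8 in control 4, against 2.82 ± 2.86 in heterozygous libraries. Itgad, the integrin CD11d, measured 5389, 357, 311 and 17.1 in the same order, against 1.82 ± 1.52. Sh2d1b1, a signalling adaptor, measured 3179, 325, 307 and 36.1, against 8.27 ± 5.54. Klrb1b, a lectin receptor, measured 379, 171.9, 72.1 and 14.02, against 2.16 ± 0.834. None of these passed the limma test over all genes (adjusted p = 0.312 for Fcrl5 and Klrb1b, 0.428 for Itgad and 0.508 for Sh2d1b1), and whether they form a group was not tested.

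In the other direction, the lectin receptor gene Cd209g measured 39.3 ± 18.4 in heterozygous libraries and at most 2.87 in control libraries, and the homeobox gene Tlx1 measured 22.6 ± 11.6 and at most 1.97. Klhl32 measured 31.3 ± 8.14 against at most 4.66 in control libraries. Their limma adjusted p was 0.0834 for Cd209g and Klhl32 and 0.138 for Tlx1. Of 19 tested immunoglobulin variable genes, 12 were lower and 7 higher in heterozygous libraries, with a median log2 difference of -0.99. The groups did not overlap in 7 of them (36.8%, against 5.14% of all tested genes and 2.86% by chance), and 0 passed the limma test (10 at an unadjusted p under 0.05). Their summed values were 567 ± 334 in control and 474 ± 319 in heterozygous mice.

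The 8 libraries can be split into 4 and 4 in 35 ways. For the number of genes changed, 1 of 35 splits (the real one) gave as many as 6 genes and the highest other split gave 1. That share is below the 0.05 set beforehand, but it is the smallest the design allows. Moreover, 4 of the 6 genes lie together at the distal end of chromosome X, and 0 genes passed with the replicate number as a block. The count therefore does not settle whether the genotype changed genes. For the number of gene lists called with the preset correlation chance was not excluded, since 17 of 35 splits gave as many as the real 19 and the highest other split gave 25. That split, control 1, control 2, control 3 and heterozygous 3 against the rest, has the 2 libraries that stood apart on the same side. For the number of genes at an unadjusted p under 0.05, the real split gave 1017 and the highest other 2741. That split sets control 1, control 4, heterozygous 1 and heterozygous 4, the 4 libraries with a hepatocyte share of at most 2.63%, against the 4 with at least 3.91%, which points to a structure of the libraries along the hepatocyte share.

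The lower values of 10 of the 11 genes at the distal end of chromosome X in heterozygous libraries were weighed against 3 explanations. A shift of the whole chromosome is argued against by the median of -0.00651 over the other 417 genes, and a different share of monocytes by a segment median of -1.005 with the monocyte list mean as a covariate. A candidate explanation is a difference in copy number, in which the control mice carried a further copy of the segment, as in the mouse strain whose Y chromosome bears a translocated distal end of X (the Yaa mutation, which duplicates Tlr7). The 5 segment genes not looked at beforehand had a median of -0.474, between the bounds set for and against it (-0.5 and -0.25), and 3 of them (Mid1, G530011O06Rik and Erdr1) lie at the pseudoautosomal boundary, so the test left it open. As all 4 controls differed from all 4 heterozygous mice, such a difference and the Ncoa5 genotype cannot be told apart here, and an effect of the genotype was not tested otherwise.

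For the higher Pf4 in heterozygous libraries, more platelets are argued against by the median of -0.546 over the other 11 measured platelet genes, and a single deviating library by the lowest log2 difference of 1.655 over the 8 fits that leave out 1 library. Both rules were written after the results were seen, so they are no independent evidence. The mean of the platelet list, Pf4 included, ran from -0.45 without control 4 to -0.13 without control 2. Reads from other cells that express Pf4 without the platelet genes were not tested. An effect of the genotype may be a candidate source of the difference, as a hypothesis, and it stays confounded with the X-linked segment.

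For the higher mitochondrially encoded transcripts in heterozygous libraries, the shortness of these transcripts is argued against by the median of 0.0818 over 3145 nuclear genes of the same transcript length (204 to 1824 bases), far below the mean of 0.96 ± 0.30 (SE over libraries). With the hepatocyte list mean as a covariate the mitochondrial mean was 0.839 ± 0.27, while the fatty acid oxidation mean went from 0.42 to 0.18. The mitochondrial mean lay above 0.5 of its value (0.48) by more than its SE, which goes against hepatocyte RNA as the whole cause. That rule was written after the results were seen, so it is no independent evidence. Under the rule written beforehand hepatocyte RNA stays open, since the SE of 0.27 reaches below the bound set against it, 0.75 of the mean (0.72). Stress during cell isolation stays open, since the mean was 0.681 ± 0.42 with the immediate early list mean as a covariate and its SE spans both bounds. An effect of the genotype was not tested otherwise.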
